A study of Mus musculus with 6 samples.

How the data were processed

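Cultured mouse uterine stromal cells of 2 genotypes were measured on 6 single-colour Affymetrix transcript arrays, 3 per genotype. Per the labels' protocols, the cells were released enzymatically from uteri taken at 4 dpc, and wells were washed after attachment to remove loose cells. They were then cultured for 24 h with estradiol (10 nM) and progesterone (1 mM as labelled, a unit that could not be checked). Amplification started from 35 ng of total RNA and used the WT-Ovation Pico and Encore modules, per the labels' protocols. Groups were taken from the sample titles, and the letter in each title (a, b or c) names the replicate. The labels do not say whether the letters are separate animals, separate pools of uteri or wells of 1 preparation. The p-values therefore measure the spread between these arrays, which may be technical.

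The deposited table holds 1 log2 value per probe set and array. The base of the logarithm was inferred from the range of the values, and the authors' background correction, normalization and summarization are not given in the sources used here. The values run up to 19.6, above the log2 ceiling of 16 that a 16-bit scanner allows, so the scale was stretched or summed before deposit and a fold change is a fold on that scale. No genome build is named, and no coordinates are given. Of 72688 rows, 6732 are control rows. Of the remaining probe sets, 30638 carry 1 gene symbol in the platform annotation, 2176 carry several and 33142 are unnamed here. Symbols were set against a gene table of the mouse assembly GRCm38.p6 through their Entrez identifiers: 22596 of 22787 matched and 0 differed. Genes with several probe sets (354) were represented by the probe set with the highest mean over the 6 arrays, which gave 30176 genes, and in 1 of the 354 the probe sets changed in both directions.

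Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, Nelfb cKO minus WT, 2-sided) on the log2 values as deposited, with no filter on dim genes. P-values were adjusted by the Benjamini-Hochberg method over all 30176 genes, with a threshold of 0.05. With 3 arrays against 3 an exact permutation test of a single gene cannot go below p = 0.10, so the calls rest on the variance that limma shares across genes. Of 30 gene lists, 29 had at least 3 measured genes and were tested with limma's camera at a preset correlation of 0.01. The same lists were tested with a correlation estimated from the data, with fry and with camera on ranks. A list's count was also computed with p-values adjusted over the list alone. The signal over background was judged against the brightest of 23 antigenomic rows on each array (4.91 to 5.99), a limit chosen after the data were examined. Between 46.4% and 72.5% of genes lay above it. Where all 3 arrays of a group lay below it, the fold is given as a lower bound, with the group's mean taken over, per array, the higher of the limit and the gene's own value.

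The lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where a sentence says otherwise. The genes named are Nelfb and the other NELF subunits. Among genes with adjusted p under 0.05 and no overlap between the groups, the 12 largest rises and the 12 largest falls are named as well, without model or clone names, small RNAs, receptor segments and olfactory or vomeronasal receptors. Up to 4 members of each list with the smallest p and 9 stromal or hormone genes fixed by name complete the rule. The alternatives were quantile normalization, a common median, the removal of genes whose higher group mean lay under the 40th percentile (log2 5.05), the mean of a gene's probe sets, trend and robust variance, array weights, the replicate letter as a block, each array left out in turn and every probe set tested on its own. Leaving members of cell type lists out of the other lists was added after the data were examined. The pseudocount alternative was not run because the table is already on a log scale.

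The procedure was tested on simulated values for the 30176 genes of Nelfb cKO against WT. It recovered 24 of 58 genes changed by 0.5 log2, 60 of 66 changed by 1 and 75 of 76 changed by 2, and 12 of 180 calls (6.67%) were false. Far fewer genes changed in the simulation (180 calls) than in the data (6304 calls), and simulated genes varied independently. The share of changed genes sets how strict the adjusted threshold is, so these rates do not carry over directly to the data. The number of arrays limits the precision of every value.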

Results

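Transcript levels were measured in uterine stromal cells from mice at 4 dpc, the time around implantation, after 24 h of culture with estradiol and progesterone, the hormones that drive decidualization, the change of stromal fibroblasts into the secretory cells that support the embryo. The arrays fall into 3 from WT cells and 3 from Nelfb cKO cells. Nelfb encodes a subunit of the negative elongation factor (NELF), the complex that holds RNA polymerase II in a paused state shortly after initiation. Array medians lay between 5.44 and 5.58 on the deposited log2 scale. Arrays correlated with others of their own group at r of 0.991 to 0.997 across probe sets and with the other group at 0.988 or below, where probe sets are not independent replicates. The lowest values within a group were those of WT replicate c, at 0.991 with each other WT array, while WT replicates a and b correlated at 0.997. No array duplicated another, since a pair shared at most 14 identical values among 72688 rows.

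The comparison asks how the transcripts of hormone-treated stromal cells differ when Nelfb is deleted. Nelfb itself was 6.90, 6.91 and 6.95 on the Nelfb cKO arrays and 8.15, 7.89 and 8.08 on the WT arrays. The mean fell by 1.12 on the log2 scale (SE 0.0826, 95% interval -1.31 to -0.92, adjusted p = 0.000106), and all 3 values lay below those of WT. The other subunits did not pass. Nelfa differed by 0.08, Nelfcd by -0.06 and Nelfe by -0.04 on the log2 scale, with adjusted p = 0.697, 0.581 and 0.867. Nelfb was read by a single probe set, and the sources used here do not say which exons were deleted, so its residual signal does not measure the share of undeleted cells.

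**Figure D1:**
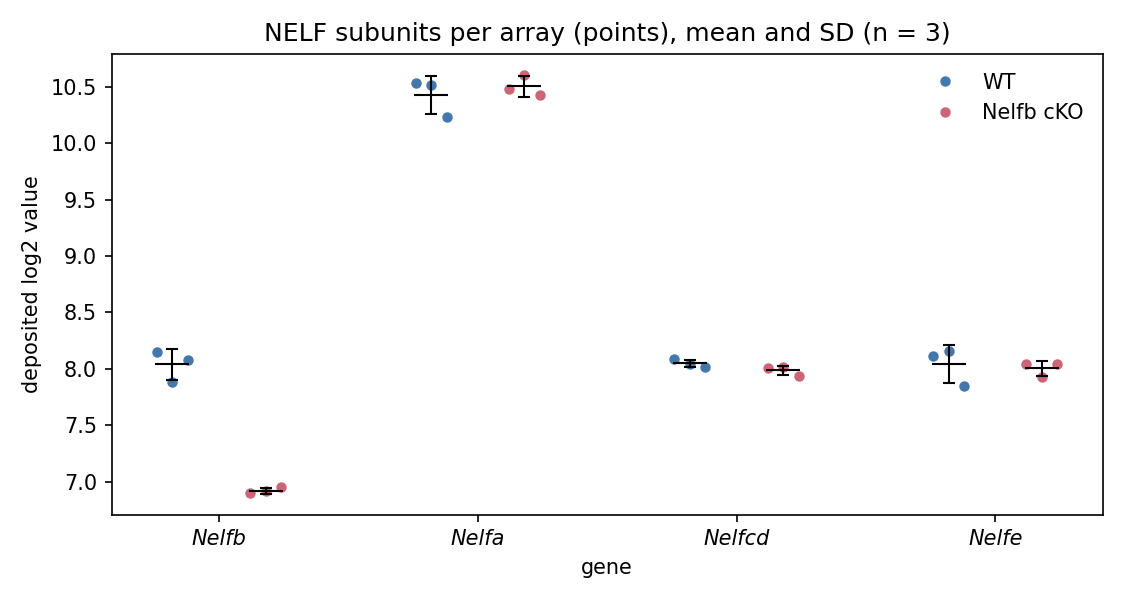
Deposited log2 values of the 4 NELF subunits (y axis) on each array, as points coloured by group, with the mean (horizontal mark) and SD (error bar, n = 3). Nelfb lay between 6.90 and 6.95 on the Nelfb cKO arrays and between 7.89 and 8.15 on the WT arrays, and the means of Nelfa, Nelfcd and Nelfe differed by 0.08 at most.

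Across the genome, 3409 genes rose and 2895 fell in Nelfb cKO cells, 6304 of 30176 in all. Of these, 550 rose and 497 fell by 1 log2 or more. The excess of rises depended on the scaling: 2430 rose and 2721 fell under quantile normalization, and 2676 and 2796 under a common median. The steepest rise was in Sprr2f, a small proline-rich protein of the cornified envelope, from 8.88 ± 0.69 to 16.87 ± 0.14 (SD, n = 3), a 254-fold rise. Sprr2b rose 117-fold, Sprr1a at least 74.0-fold from a WT level below background, the calcium-binding S100g 101-fold, the secreted proline-rich Prap1 70.6-fold and the chloride channel regulator Clca3b 57.1-fold. The Sprr2 genes are near-identical copies, so the split of signal among them is uncertain. The others among the 12 largest rises were Prl8a2 (170-fold), the platelet chemokine Ppbp (126-fold), the imprinted retrotransposon-derived Peg10 (55.1-fold), the endogenous retroviral Erv3 (37.7-fold), the oxidized LDL receptor Olr1 (34.2-fold) and the cytokine Il1a (31.4-fold).

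The steepest fall was in Hsd11b2, the enzyme that inactivates glucocorticoids, from 13.31 ± 0.39 to 8.10 ± 0.14 (SD, n = 3), a 37.0-fold drop with adjusted p = 6.52e-06. Also lower were the heparin-binding growth factor Ptn (log2 difference -3.68), neuropeptide Npy (-3.61), the fatty acid desaturase Scd1 (-3.32) and the Rho regulator Arhgap20 (-3.31). The matrix genes Prelp, Ltbp2, Vit and Lama4 differed by -3.22, -3.20, -3.04 and -3.02, the linker histone H1f5 by -3.06, the actin-binding Ablim3 by -3.06 and Parm1 by -2.94. In 6302 of the 6304 changed genes the groups did not overlap. Over all genes 36.0% showed no overlap, where chance gives 10%.

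Epithelial, myeloid and endothelial markers were higher on the Nelfb cKO arrays. Many were dim in WT: 7 of 21 epithelial, 12 of 18 myeloid and 5 of 15 endothelial markers lay above background on all 3 WT arrays. Of 21 epithelial markers 20 rose (20 when adjusted over the list alone), with a median of 1.92 log2. Lactoferrin (Ltf) rose by 4.58, the stem cell antigen Prom1 by 3.19, keratin Krt19 by 2.66 and the epithelial transcription factor Elf3 by 2.02. The list passed camera at adjusted p = 1.08e-22, with adjusted p = 0.169 with an estimated correlation. Of 18 macrophage and myeloid markers 15 rose and 0 fell (16 when adjusted over the list alone, median 1.25), among them Cd68 by 2.19, Cd14 by 1.90, lysozyme Lyz2 by 1.58 and Itgam by 1.19 (camera adjusted p = 1.52e-12, and adjusted p = 0.169 with an estimated correlation). Of 15 endothelial markers 8 rose and 1 fell (10 and 1 when adjusted over the list alone, median 0.46), led by the VEGF receptor Kdr at 2.84 and Emcn at 1.29, with camera adjusted p = 4.41e-05 and adjusted p = 0.175 with an estimated correlation.

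Stromal markers did not shift as a list. Of 15, 4 rose and 7 fell (4 and 8 when adjusted over the list alone), with a median of -0.22, a mean of 0.02 and camera adjusted p = 0.132. Thy1 (log2 difference -1.87) and Wt1 (-0.82) were lower, while the proteoglycans Dcn and Lum rose by 1.97 and 1.75. Smooth muscle and pericyte markers were lower, with 10 of 14 down and 2 up (the same numbers when adjusted over the list alone, median -0.59). The log2 differences were -1.46 for Actg2, -1.29 for Synpo2, -1.07 for Smtn and -1.02 for Mylk (camera adjusted p = 2.94e-06, and adjusted p = 0.287 with an estimated correlation). NK and T cell, mesothelial, trophoblast and red blood cell lists did not pass (camera adjusted p = 0.393, 0.117, 0.476 and 0.831). Their changed members were Ccl5 in the first (1 of 14), Msln and Krt19 up with Wt1 down in the second (of 9), Krt7 and Tpbpa in the third (2 of 11) and 0 of 3 in the last, and adjustment over the list alone gave the same counts.

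Decidualization genes moved in both directions. Of 35 measured, 13 rose and 10 fell (13 and 11 when adjusted over the list alone), with a median of 0.05 and camera adjusted p = 0.480. Prl8a2, a prolactin-family hormone of decidual cells, went from 6.88 ± 0.35 to 14.29 ± 0.14 (SD, n = 3), a 170-fold rise with adjusted p = 1.42e-06. Cebpb, a transcription factor of decidualization, rose by 0.53. Lower were the prostaglandin E synthase Ptges (log2 difference -1.80), the heparin-binding growth factor Hbegf (-1.34), the activin-binding protein Fst (-1.02), the progesterone-responsive regulator Hand2 (-0.42) and Wnt4 (-0.41). The morphogen Bmp2 fell by 0.56 with adjusted p = 0.0490, a call that was lost in 9 of 13 alternatives (adjusted p from 0.00264 to 0.140), and the fall of Wnt4 was lost in 2 (adjusted p from 0.00844 to 0.0535). The homeobox gene Hoxa10 differed by 0.13 with adjusted p = 0.459.

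Hormone receptors were lower and their target lists mixed. The progesterone receptor Pgr differed by -0.35 and the estrogen receptor Esr1 by -0.43 on the log2 scale (adjusted p = 0.00650 and 0.00682). On the same arrays the stromal median was -0.22, and the epithelial and myeloid medians were 1.92 and 1.25 higher. Of 22 progesterone receptor targets 9 rose and 5 fell (10 and 5 when adjusted over the list alone, median 0.18, camera adjusted p = 0.132). Cited2 rose by 2.12, the kinase Sgk1 by 1.58 and the insulin receptor substrate Irs2 by 1.57, Hsd11b2 fell as above, and the glucocorticoid and progesterone target Fkbp5 differed by -0.04 with adjusted p = 0.791. Of 19 estrogen receptor targets 11 rose and 5 fell, in both adjustments (median 0.37, camera adjusted p = 0.00900, and adjusted p = 0.240 with an estimated correlation). Prap1, Ltf, lipocalin Lcn2 (up by 3.55) and mucin Muc1 (up by 2.89) led, and Ltf and Muc1 also stand in the epithelial list, whose median was 1.92 higher on the same arrays. In a setting added after the data were examined, the estrogen list without those 2 members had 9 of 17 genes up and 5 down with a median of 0.30, and did not pass (adjusted p = 0.128). The progesterone list without its 2 shared members had 9 of 20 up and 3 down with a median of 0.22, and passed (camera adjusted p = 0.0248). Those members, Hand2 (-0.42) and Nr2f2 (-0.29), were both among the 5 that fell, so their removal itself raised the list. With an estimated correlation the full list had adjusted p = 0.527, and the reduced list was not tested that way.

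**Figure D2:**
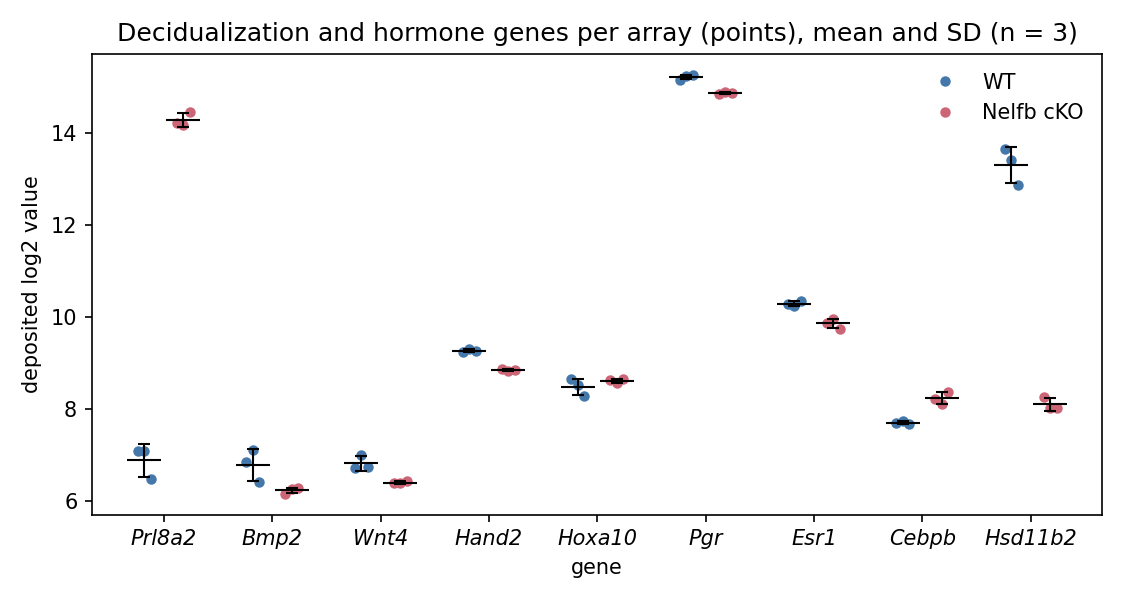
Deposited log2 values of 9 decidualization and hormone genes (y axis) on each array, as points coloured by group, with the mean (horizontal mark) and SD (error bar, n = 3). Prl8a2 averaged 6.88 in WT and 14.29 in Nelfb cKO cells, Hsd11b2 averaged 13.31 and 8.10, and the remaining genes differed by less than 1 log2.

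Cell cycle genes were lower together. Of 35 genes of G2/M and mitosis 33 fell and 0 rose (34 and 0 when adjusted over the list alone), with a median of -1.25. The log2 difference was -2.39 for the proliferation marker Mki67, -2.23 for topoisomerase Top2a, -2.10 for anillin (Anln) and -1.53 for cyclin Ccna2. Of 38 genes of G1/S and DNA replication 33 fell and 1 rose (37 and 1 when adjusted over the list alone, median -1.07), among them cyclin Ccne2 (-1.73), the polymerase subunits Pole (-1.55) and Pola1 (-1.27) and the licensing factor Cdc6 (-1.28). Camera gave adjusted p = 7.72e-29 and 9.18e-25, and adjusted p = 0.169 with an estimated correlation for each. DNA repair and checkpoint genes fell in 21 of 27 cases and rose in 1 (22 and 1 when adjusted over the list alone, median -0.48, camera adjusted p = 4.11e-13, and adjusted p = 0.169 with an estimated correlation), including Clspn (-1.84), Exo1 (-1.16), Topbp1 (-1.07) and Rad50 (-1.03).

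Replication-dependent histones fell in 13 of 25 cases and rose in 1 (17 and 2 when adjusted over the list alone, median -0.56), with H2ac15 at -2.04 and H2bc12 at -1.43 (camera adjusted p = 2.57e-07, and adjusted p = 0.169 with an estimated correlation). The list also took in H1f10 (0.08, adjusted p = 0.515), which does not depend on replication, and left out the linker histones H1f2, which rose by 3.71, H1f3, which rose by 0.38, and H1f5 (H1f10, H1f2 and H1f3 are named here after their values were seen). Among 14 D-type cyclins, their kinases and inhibitors, 5 fell and 2 rose (8 and 2 when adjusted over the list alone, median -0.25). Ccnd2, Cdk6 and Rbl1 differed by -1.67, -1.42 and -0.63, and the inhibitor Cdkn1c rose by 1.07 (camera adjusted p = 0.00673, and adjusted p = 0.287 with an estimated correlation). The 23 p53 targets split into 6 up and 9 down (6 and 11 when adjusted over the list alone, median -0.11, camera adjusted p = 0.0774), with Plk2 up by 2.26, Perp by 1.38 and Btg2 by 0.70, and Ccng1 at -1.17. The epithelial and myeloid medians were 1.92 and 1.25 higher on the arrays on which these cell cycle genes fell.

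Sterol and glucose metabolism genes fell on arrays on which the epithelial and myeloid medians were 1.92 and 1.25 higher and the smooth muscle median was -0.59. Of 18 cholesterol synthesis genes 16 fell and 0 rose, in both adjustments, with a median of -1.13. Among them were lanosterol synthase Lss (-2.14), Nsdhl (-1.90), the sterol carrier Stard4 (-1.63) and mevalonate kinase Mvk (-1.60), with log2 differences in parentheses (camera adjusted p = 8.52e-18, and adjusted p = 0.169 with an estimated correlation). Of 25 glycolysis and hypoxia genes 20 fell and 0 rose (22 and 0 when adjusted over the list alone, median -0.67), including the kinases Pdk1 (-1.78) and Pfkl (-1.77) and the collagen prolyl hydroxylases P4ha2 (-1.58) and P4ha1 (-1.18), with camera adjusted p = 1.27e-16 and adjusted p = 0.169 with an estimated correlation. Unfolded protein and ATF4 response genes fell in 13 of 23 cases and rose in 4 (15 and 4 when adjusted over the list alone, median -0.37). Creld2 differed by -1.61, the serine synthesis enzyme Phgdh by -1.24 and the chaperone Hsp90b1 by -0.85, while Dnajb9 rose by 1.21 (camera adjusted p = 6.82e-05, and adjusted p = 0.346 with an estimated correlation).

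Inflammatory, interferon and immediate early genes rose, on the same arrays on which the myeloid median was 1.25 higher. Of 31 NF-kB and cytokine genes 20 rose and 1 fell (22 and 2 when adjusted over the list alone, median 0.66), with camera adjusted p = 6.38e-10 and adjusted p = 0.175 with an estimated correlation. The smallest p-values belonged to Lcn2, Il1a and the chemokines Ccl7 (up by 1.64) and Ccl5 (up by 2.11). Cxcl5, Cxcl2 and Cxcl3 rose by more than Ccl7 (2.08, 1.93 and 1.67). Of 33 interferon-stimulated genes 27 rose and 0 fell (29 and 0 when adjusted over the list alone, median 0.79). The nucleic acid sensor Zbp1 rose by 2.53, Ifit3 by 2.26, Rtp4 by 2.00 and viperin (Rsad2) by 0.90 (camera adjusted p = 1.99e-13, and adjusted p = 0.240 with an estimated correlation). Of 31 immediate early genes 23 rose and 3 fell (25 and 3 when adjusted over the list alone, median 0.64), with Egr1 up by 2.99, Trib1 by 1.54 and Fosb by 1.10 (camera adjusted p = 2.27e-10, and adjusted p = 0.175 with an estimated correlation).

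Matrix genes moved in both directions, on the same arrays with higher epithelial and myeloid medians (1.92 and 1.25) and a smooth muscle median of -0.59. Of 39 extracellular matrix and remodelling genes 15 fell and 9 rose (18 and 10 when adjusted over the list alone, median -0.17). The collagens Col1a1 and Col12a1 differed by -2.51 and -1.97 and biglycan (Bgn) by -2.44, while stromelysin Mmp3 rose by 3.26 (camera adjusted p = 0.00614, and adjusted p = 0.527 with an estimated correlation). TGF-beta and SMAD targets split into 5 up and 5 down of 17 (8 and 5 when adjusted over the list alone, camera adjusted p = 0.774). Their median was 0.15 and their mean -0.08, with the ligand Tgfb3 at -1.75, Smad6 at -0.61 and Ltbp2 as above, and the repressor Tgif1 higher by 1.03.

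The pausing machinery and the heat shock genes did not pass camera as lists, but fry called both higher (adjusted p = 0.0234 and 0.0372). Of 15 NELF, DSIF and pause-release factors 5 rose and 2 fell (6 and 2 when adjusted over the list alone, median 0.08, camera adjusted p = 0.228). The 2 that fell were the deleted gene itself, Nelfb (-1.12), and Hexim1 (-0.38), so the deletion pulls against the list's rises. The elongation factors Ell2 and Aff4 rose by 1.54 and 0.48 and the termination factor Pcf11 by 0.49. Of 15 heat shock genes 5 rose and 4 fell (5 and 5 when adjusted over the list alone, median 0.07, camera adjusted p = 0.476), with Hspa1a up by 1.33, Hspb1 by 1.25 and Hspa4 by 0.55, and Hspb8 at -0.86. Ribosomal protein genes fell in 10 of 41 cases and rose in 0, in both adjustments, with a median of -0.16 (camera adjusted p = 8.32e-06, and adjusted p = 0.287 with an estimated correlation). Rpl22l1 differed by -0.60 and Rpl12 by -0.39. The 2 mitochondrial transcripts were too few to test as a list, and neither passed (mt-Rnr1 differed by -0.01 and mt-Tk by -0.28).

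**Figure D3:**
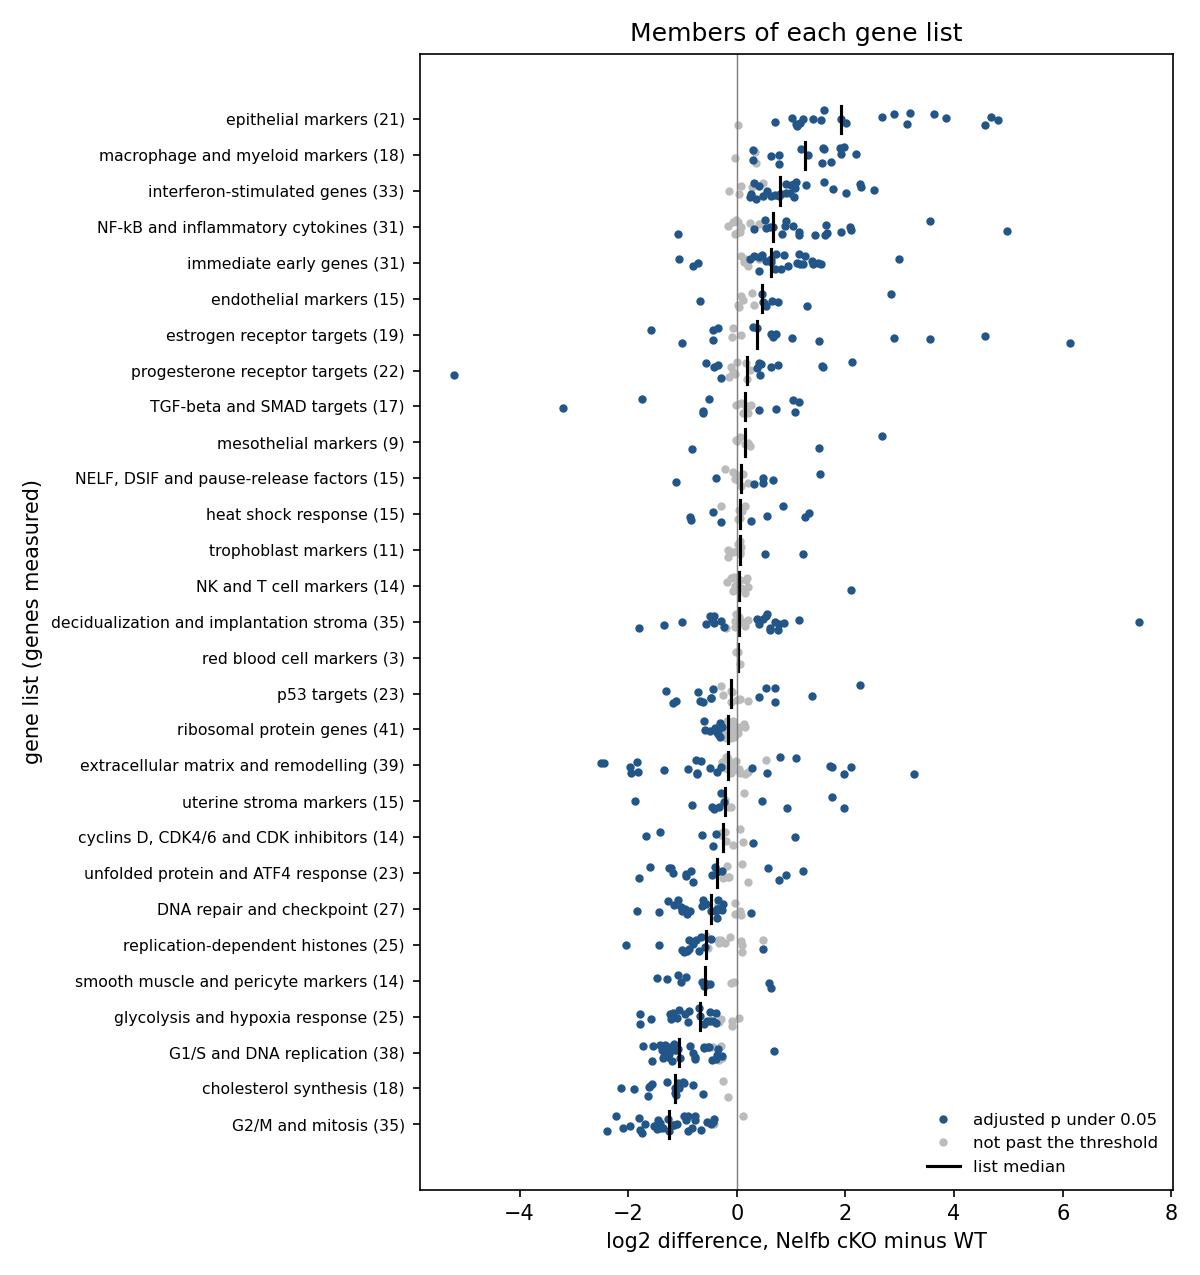
Log2 differences (x axis, Nelfb cKO minus WT) of the measured members of the 29 tested gene lists (y axis, with the number measured), ordered by median. Points are genes, dark where adjusted p was under 0.05, and vertical marks are list medians, which run from -1.25 for G2/M and mitosis to 1.92 for epithelial markers.

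In all, 18 of 29 lists passed camera, 7 up and 11 down, and 0 of the 18 passed with an estimated correlation. The labels do not say how the cultures were divided among preparations, so no value within a preparation could be computed.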

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

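All tests of Prl8a2 and of the cell cycle genes below, and the test of array scaling for the epithelial markers, were chosen after the results were seen, and the tests with second marker lists and with other splits were written before their values were seen.

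Outside the genes tested, 973 probe sets with no symbol here and 144 probe sets with several symbols were higher in Nelfb cKO than in WT cells, and 573 and 159 were lower. In all, 1546 of 33142 and 303 of 2176 changed, smaller shares than the 6304 of 30176 genes tested. These probe sets hold signal that the comparison of named genes does not use.

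The count of 6304 changed genes and the count of 18 shifted lists were set against the other splits of the 6 arrays into 3 and 3. There are 10 splits, too few for a share under 0.05. The real split was the 1 split with as many changed genes, and the highest count among the others was 0 genes. It was also the 1 split with as many shifted lists, and the highest count among the others was 14. Every other split mixes WT and Nelfb cKO arrays, so a difference between the genotypes widens the spread within its groups. The mix is uneven in each of them, so part of that difference also stays between their groups. The low gene counts of those splits therefore do not speak on chance, and their list counts are no null rate for camera.

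Epithelial markers were higher in Nelfb cKO cells, with a list median of 1.92 log2. The cytokeratins Krt8 and Krt18, chosen for their abundance after their values were seen, rose from 6.54 and 6.67 to 11.3 and 11.3. Scaling of the deposited arrays as a whole is argued against: their transcript medians lay between 5.37 and 5.48, and the lowest list median under another scaling was 1.86. With array medians this close the other scalings could move the list little, so they do not test the authors' own processing. More epithelial cells in the Nelfb cKO cultures are a candidate explanation: 68.8% of a second epithelial list (22 of 32 genes) rose as well, though its median of 0.40 log2 was smaller than the first list's. Of these 32 genes, 1 lay above background on all 3 WT arrays and 0 stood in the first lists, and the washes after attachment would remove only loose cells. A switch-on of epithelial genes within stromal cells by the loss of Nelfb stays open. In a second myeloid list 81.2% of genes rose (26 of 32, of which 19 were above background on all 3 WT arrays), so more than the epithelial type differed, but arrays of mixed RNA cannot say which cells a transcript came from.

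Cell cycle genes were lower in Nelfb cKO cells, with a G2/M median of -1.25. Dilution of stromal RNA by RNA of other cells is argued against as the whole cause: the stromal list's median was -0.22. Of its 15 markers 4 rose and 7 fell, so the median gauges the stromal share only roughly. The bootstrap interval (10000 resamples of genes) of the stromal median ran from -0.42 to 0.13, wholly above that of the G2/M list (-1.45 to -0.90). Resampling took genes as independent, though their estimated correlations were 0.24 and 0.50. The intervals are therefore too narrow and hold no spread between arrays. Scaling of the deposited arrays as a whole is argued against too, since their transcript medians lay between 5.37 and 5.48. With medians this close the other scalings could move the list little (the highest G2/M median was -1.29), so they do not test the authors' own processing. A difference between the 2 sets of cultures other than the genotype, such as their density or the number of cells that attached, stays open. The groups share 0 title numbers, but the number follows the genotype and no label says what it marks, so it decides nothing. An effect of Nelfb loss on proliferation is thus a hypothesis that these data leave open.

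Prl8a2 was 7.41 log2 higher in Nelfb cKO cells. Signal from another measured member of the prolactin family is argued against, since the largest rise among the other 21 measured members was 0.48 (Prl3c1, below background on all 3 WT arrays). Members not measured, Prl3d1 and Prl3b1 among them, could not be judged, so signal from those stays open. Cells of the conceptus carried into the cultures are argued against only in part by the trophoblast list, of which 18.2% rose (Krt7, also an epithelial marker, and Tpbpa). Of its 11 measured genes 6 stayed below background in both groups. A further 3 markers, among them the placental prolactins Prl3d1 and Prl3b1, were not measured, so the list cannot exclude such cells. Peg10, a gene that placenta also expresses, rose by 5.78 and goes the other way. A more advanced decidual state of the Nelfb cKO cells may be involved but stays open: of the other 34 decidualization genes 35.3% rose (12) and 10 fell.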

How the results depend on the processing

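The alternative that leaves out members of cell type lists was chosen after the data were seen. The count of changed genes stayed within 1.5 times of 6304 in every alternative run (4708 to 7524), with the share of higher genes between 47.2% and 55.2% in the alternatives run per gene, and leaving out 1 array gave 4708 to 6647. Nelfb stayed lower and past the threshold throughout (-1.19 to -1.06 without 1 array). The 18 shifted lists were 17 to 26 in the other alternatives and 0 with an estimated correlation. Whether the letters pair the arrays is unresolved. Deviations of same-letter arrays correlated at 0.19, 0.03 and 0.27 for a, b and c, where the highest values with another letter were 0.09, 0.10 and -0.09. Thus a and c, but not b, correlated best with their own letter. With the replicate block 6422 genes changed and Bmp2 alone among the named genes and lists lost its call. Lists weakened in 20 comparisons (18 with an estimated correlation, the others being the estrogen receptor targets on ranks and without cell type members) and strengthened in 9 (7 with fry), and named genes weakened in 11 (Bmp2 in 9, Wnt4 in 2); the cause was not tested. The named genes and the red blood cell list that turned direction were past the threshold in 0 settings. The medians of the decidualization and trophoblast lists were -0.0013 under quantile normalization and -0.016 without Nelfb cKO replicate c, with the test's direction kept, and both lists passed with fry alone (adjusted p = 0.0367 and 0.00239, up to 0.777 and 0.634 in the other alternatives). Slc4a1 was -0.0088 and -0.019 under quantile normalization and a common median, the red blood cell list -0.019 under a common median, and Alas2 0.035 with array weights. The TGF-beta list, at a median of 0.15, was called lower by fry (adjusted p = 0.0300, against 0.0300 to 0.982 over its alternatives), in the direction of its mean. Without 1 array, Nelfa ran from -0.021 to 0.129, Nelfe from -0.134 to 0.023, Slc4a1 from -0.013 to 0.048, Alas2 from -0.069 to 0.084, mt-Rnr1 from -0.046 to 0.053 and the red blood cell list from -0.013 to 0.083. Signal over background limits the dim lists: 8 of 14 NK and T cell and 6 of 11 trophoblast markers lay below background in both groups.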

Other observations

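The gene families in this part were chosen after the data were examined. The enzymes that set local glucocorticoid levels moved in opposite directions: Hsd11b1, which regenerates active glucocorticoid, rose by 1.88 log2 (adjusted p = 6.85e-05), and Hsd11b2, which inactivates it, fell by 5.21. Fatty acid desaturase genes were lower as well. Of 8 Fads and Scd genes 6 fell, including Scd1 (log2 difference -3.32), Fads2 (-2.16), Fads3 (-2.10) and Fads1 (-1.63), and Fads2b and Fads6 rose from levels near background (1 of them passed under quantile normalization and both under a common median). Laminin genes moved in both directions. Lama4, Lama2 and Lamb2 differed by -3.02, -2.57 and -2.28, and Lamc1, Lamb1 and Lama5 by -0.90, -0.72 and -0.32, while Lama3 rose by 0.98 and Lamb3 at least 1.00-fold from a WT level below background. Of the 10 laminin genes 6 fell and 2 rose, or 5 and 2 under quantile normalization and 6 and 2 under a common median.

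Of 35 Ccl and Cxcl genes with Pf4 and Ppbp, 19 rose, 1 (Cxcl14) fell and 15 did not pass, with a median of 0.57, and the counts were 16 and 2 under quantile normalization and 17 and 1 under a common median. The platelet chemokines Ppbp and Pf4 rose by 6.98 and 3.14, Cxcl16 by 2.01 and Ccl3 by 1.93. The epithelial and myeloid medians were 1.92 and 1.25 higher on the same arrays. Of 13 Sprr genes 9 rose and 0 fell under all 3 scalings, on the arrays on which 20 of 21 epithelial markers rose. Among the 9, Sprr2i lay below background in both groups. Among 8 linker histone genes, H1f2 rose by 3.71 and H1f3 by 0.38, H1f5 fell by 3.06, and 5 did not pass, among them H1f1 at -0.56 (adjusted p = 0.0595). The counts of 2 up and 1 down became 1 and 2 under quantile normalization and 2 and 2 under a common median. Of 1224 olfactory receptor genes, 860 lay below background in both groups, and 12 were called higher and 16 lower (2.29%), or 8 and 14 under quantile normalization and 7 and 16 under a common median.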
